A study of Homo sapiens and Mus musculus with 36 samples.

How the data were processed

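RNA was sequenced from 36 libraries in 18 groups of 2, with groups taken from the sample labels. Per the labels' protocols, libraries were made with TruSeq v2 or NEBNext Ultra II kits, without saying which library used which. Per the submitters' processing notes, the tools included STAR 2.4.2 and Salmon (version not given in the sources used here), with the genome builds GRCh38 and mm10; strand and further settings are not given in the sources used here. In 12 of the 13 tables only the authors' own comparison was analysed here. Per the file headers, these hold a mean normalized signal per gene, a log2 fold change over the control with its standard error, a test statistic (a score: the fold change divided by its standard error), a p-value and an adjusted p-value in the layout of DESeq2. That the statistic equals the fold change over its standard error, and that adjusted p-values follow the Benjamini-Hochberg method, was checked in each deposited table. The Huh7 shEZH2 table also holds the authors' estimated counts per library from Salmon, which need not be whole.

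Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood, TMM normalization, R 4.3.3), Huh7 shEZH2 against its control, with no block; the groups held 2 libraries each. The design fixed before the data were examined called for edgeR on whole counts per library, or limma on the log2 scale for normalized values per library. Otherwise it called for the authors' deposited values at an adjusted p under 0.05. These counts were not whole, and normalized values were given beside them, so edgeR on rounded counts departs from that design. The edgeR test covers 1 comparison. The standard error (SE) printed with edgeR values was derived as the size of the log2 fold change over the root of the quasi-likelihood F statistic. For EZH2 it was 0.08, against 0.12 in the authors' deposited table. Of the 15228 rows of that table, 20 carried dates in place of gene symbols and were left out. The 2 libraries of each group differed little beyond sampling, and the common biological coefficient of variation was 0.0187.

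The sign of the deposited fold changes was checked by rebuilding each gene's control level from its mean and fold change. Tables that share control libraries gave matching control levels only as deposited, with an interquartile range of 0.00172 on the log2 scale between the HepG2 shEZH2 and #664 tables and 0.949 with the shEZH2 sign turned. Huh7 MS7126 has no such partner, and its direction rests on the series' description.

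Gene lists, 31 in all, were fixed before the data were examined and tested with limma 3.58.1 cameraPR on the test statistic of genes with a mean of at least 10 normalized counts, with an inter-gene correlation of 0.01, for lists with at least 5 measured members. Adjustment ran over 357 tests, of which 132 passed. Where the text gives a count of members, it is over all genes tested, and beside it the count adjusted over the list alone. For Huh7 shEZH2, camera was also run with an estimated correlation. Its p-values were adjusted together with those of the other comparisons at the preset correlation, not over the Huh7 shEZH2 lists alone. Differences between comparisons were tested as the difference of log2 fold changes over the root of the summed variances, which ignores the covariance of shared controls. Differences and overlaps that involve Huh7 shEZH2 used the authors' deposited values for it, and edgeR values as an alternative chosen after seeing the data. Overlaps were set beside those of independent lists and, for shared controls, beside 100 simulations of unchanged groups. The genes named were chosen by a rule fixed before the data were examined: the targeted gene, the highest and lowest log2 fold changes (6 each, or 4 each for the minor comparisons) among called genes with a mean of at least 100 normalized counts, up to 4 members with the smallest adjusted p of each passing or central list, and 5 differences each way. Not all of these are printed, some genes are not reported here, and the lists drawn in the plot of gene lists were picked after their results were seen. HMGCS1, SQLE, EZH2, ASNS and, except between the libraries labelled shEZH2 and #667, SREBF2 are given for differences although that rule does not name them there, and were chosen after values had been seen. Coordinates are 1-based from the GENCODE annotation of GRCh38.

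The edgeR, cameraPR and difference steps were tested on simulated data, and camera was not. In counts drawn from the means of Huh7 shEZH2 and its control (14473 genes), edgeR recovered 96 of 109 genes changed 2-fold and 87 of 89 changed 4-fold, with 26 false calls of 211, above the nominal share. On the same simulated comparison cameraPR gave a seeded list p of 7.16e-11 and 1 of 200 random lists a p under 0.05. Genes were drawn independently there, so this does not test the inter-gene correlation. With variances added, the difference step on 14026 genes recovered 45 of 99 genes differing 2-fold and 75 of 92 differing 4-fold with 0 false calls of 120, and is conservative where controls are shared. A floor on the simulated dispersion gave all these counts more spread than the Huh7 shEZH2 libraries, whose common biological coefficient of variation was 0.0187. The rates of recovery and of false calls need not hold for the data themselves.

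The alternatives tried were a 2-fold minimum, an adjusted p under 0.01, other filters on low counts, centring, DESeq2 1.42.0 and the replicate number as a block for Huh7 shEZH2, leaving out each library there, another inter-gene correlation, ranks, random lists matched on expression (10000 draws), and a covariance for shared controls. The random lists were drawn from genes near in expression rank and could hold a list's own members. The depth of single libraries is known only for Huh7 shEZH2. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.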

Results

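The series measured RNA levels by sequencing in HepG2 and Huh7, which are human liver cancer cell lines, and in WEHI-231, a mouse B-lymphoma cell line. The 36 libraries fell into 18 groups of 2. MS7126 and MS8815 are named as PROTACs against EZH2, the histone methyltransferase subunit of the Polycomb complex PRC2; a PROTAC is a molecule built to have its target protein degraded. C24 is named as the matched inhibitor of MS7126, and MS7126N1 and MS7126N2 as analogs of MS7126 without PROTAC activity. EPZ-6438 is an EZH2 inhibitor, and MS8815N is the analog of MS8815 without PROTAC activity. HepG2 cells received 5 uM of a compound or DMSO for 48 h, Huh7 cells 5 uM MS7126 or DMSO for 24 h by their own label, and WEHI-231 cells 1 uM of a compound or DMSO for 16 h. A label of the WEHI-231 samples gives another time for Huh7, so that time is uncertain. By their labels, the remaining groups carried short hairpins against EZH2 (HepG2, Huh7) or against SREBF2 (HepG2, hairpins #664, #665 and #667). SREBF2 is the gene of SREBP2, a transcription factor regulated by sterols. All 4 HepG2 hairpin groups share 1 pair of control libraries, and the labels call the control both an empty vector and a scrambled hairpin.

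Values per library were analysed here for 1 comparison, Huh7 shEZH2, whose libraries summed to 11300070 and 10106193 estimated counts (controls) and 11240538 and 11954322 (shEZH2). The other 12 comparisons rest on the authors' deposited table of each, with a log2 fold change, a standard error (SE) and an adjusted p per gene. The mean normalized counts in each of the authors' deposited tables for these 12 summed to between 16686567 for HepG2 C24 and 40979203 for HepG2 #664. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which can be technical. In Huh7 shEZH2 the libraries of a group differed little more than sampling allows, with a chi-square per degree of freedom of 1.42 in the controls and 1.36 in shEZH2.

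**Figure D1:**
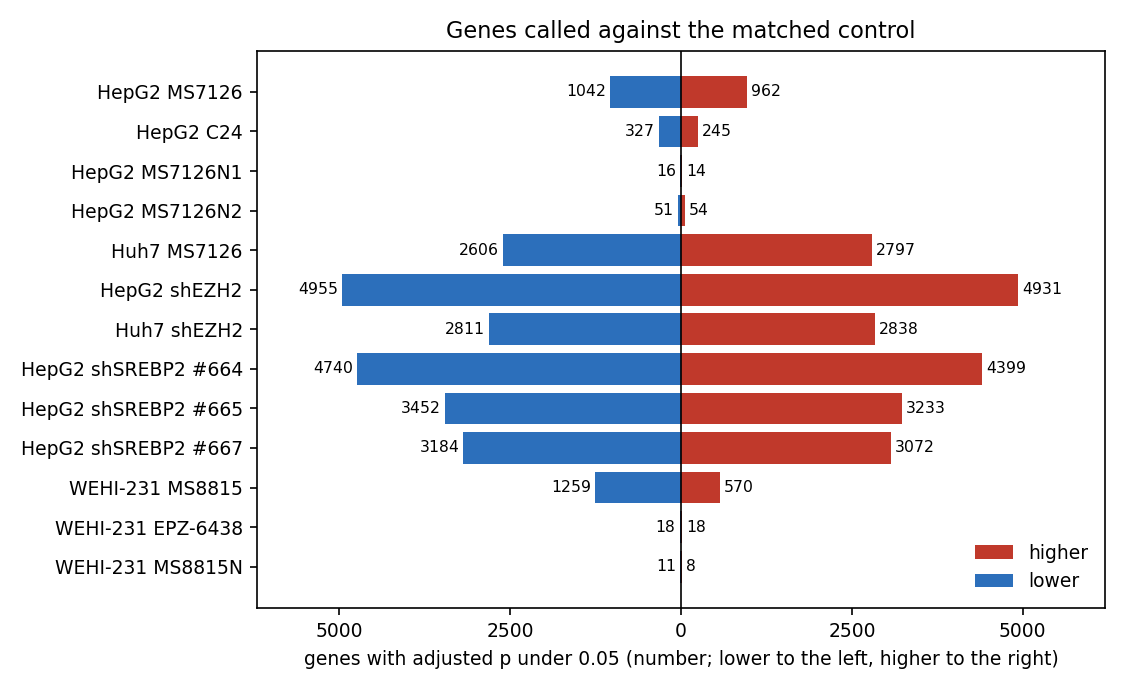
Number of genes with an adjusted p under 0.05 in each comparison, lower than control to the left and higher to the right. HepG2 libraries labelled shEZH2 gave 4931 higher and 4955 lower genes, and the analogs MS7126N1 and MS8815N gave 30 and 19 genes in all.

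The targeted genes were read first. EZH2 (GRCh38 chromosome 7, 148807383 to 148884321, minus strand) fell in Huh7 shEZH2 from 960 ± 55.3 to 152 ± 5.2 normalized counts (SD, n = 2 each), to 15.9% of control, a log2 fold change of -2.65 (SE 0.08, edgeR adjusted p = 3.03e-13). In the HepG2 libraries labelled shEZH2, the authors' deposited table gave EZH2 a log2 fold change of 0.90 (SE 0.38, adjusted p = 0.0337), higher than control. That SE lay 2.04 on the log2 scale above the trend of SE with mean count, and the SE of SREBF2 lay 2.64 above it in the same table. The label and the level of its target go against each other there, and every direction given below for these libraries carries that limit. SREBF2 (chromosome 22, 41833079 to 41907308, plus strand) fell in each SREBP2 hairpin, with log2 fold changes in the authors' deposited tables of -1.58 (SE 0.06) for #664, -1.08 (SE 0.12) for #665 and -2.35 (SE 0.42) for #667. The SE for #667 lay 1.91 on the log2 scale above the trend. The compounds act on protein, so EZH2 mRNA is no check of them. EZH2 mRNA was lower under MS7126 in Huh7 (-0.46, SE 0.13) and under MS8815 (-0.24, SE 0.07) in the authors' deposited tables, and was not called under the other compounds.

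MS7126 in HepG2 asked what the PROTAC does to the transcriptome of these cells. Genes of cholesterol synthesis were lower: 19 of 21 measured members fell and none rose, with a median log2 fold change of -1.35 (cameraPR adjusted p = 1.29e-36), and the count adjusted over the list alone was also 19. The authors' deposited table gave ACAT2 -1.92 (SE 0.16), the squalene epoxidase gene SQLE (chromosome 8, 124998497 to 125022283, plus strand) -1.87 (SE 0.16), FDFT1 -1.60 (SE 0.17) and DHCR7 -1.32 (SE 0.14). Among 9 sterol-responsive genes outside synthesis, 4 fell and none rose (5 adjusted over the list alone, cameraPR adjusted p = 3.35e-05). In the authors' deposited table TMEM97 stood at -1.35 (SE 0.17). Fatty acid synthesis had 8 of 16 members lower and 2 higher (8 and 2 adjusted over the list alone, cameraPR adjusted p = 4.92e-08), with SCD at -1.82 (SE 0.12) and FADS1 at -1.63 (SE 0.15) in the authors' deposited table.

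Targets of ATF4, a transcription factor of the amino acid and stress response, rose under MS7126 in HepG2: 23 of 25 were higher (25 adjusted over the list alone), with a median of 1.65 (cameraPR adjusted p = 3.87e-74). The authors' deposited table gave the asparagine synthetase gene ASNS 3.29 (SE 0.17), TRIB3 2.71 (SE 0.14), the cystine transporter gene SLC7A11 2.70 (SE 0.20) and GDF15 1.67 (SE 0.13). NRF2 targets had 11 of 18 members higher and 1 lower (11 and 1 adjusted over the list alone, cameraPR adjusted p = 2.42e-17), and p53 targets 11 of 22 higher and none lower (11 adjusted over the list alone, cameraPR adjusted p = 1.87e-07). Immediate early genes had 7 of 10 higher (8 adjusted over the list alone, cameraPR adjusted p = 1.85e-13), with EGR1 at 2.62 (SE 0.26) in the authors' deposited table. DNA replication genes fell, 19 of 33 lower (26 adjusted over the list alone, cameraPR adjusted p = 1.34e-14), as did mitosis genes, 20 of 28 lower (25 adjusted over the list alone, cameraPR adjusted p = 7.13e-18). PCNA stood at -0.99 (SE 0.16), TOP2A at -1.20 (SE 0.16) and CENPE at -1.89 (SE 0.19) in the authors' deposited table. Hepatocyte markers had 11 of 22 lower and 2 higher (12 and 3 adjusted over the list alone, cameraPR adjusted p = 4.42e-17), with APOA1 at -1.87 (SE 0.12) and APOC3 at -2.11 (SE 0.17) in the authors' deposited table. Genes described elsewhere as PRC2-repressed did not pass as a list in this or any other comparison, although IGFBP3 stood at 3.99 (SE 0.67) in the authors' deposited table.

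In all, the authors' deposited table held 962 higher and 1042 lower genes of 12923 tested for HepG2 MS7126 (428 and 422 at 2-fold or more). Among called genes with a mean of at least 100, the largest increases in the authors' deposited table were KLHDC7B 8.01 (SE 1.09), IGFBP1 4.59 (SE 0.20), AQP3 4.32 (SE 0.35), ARRDC4 3.61 (SE 0.35), PLA2G12A 3.50 (SE 0.30) and ANGPTL8 3.33 (SE 0.29). Among the lowest in the authors' deposited table were RAB12 at -10.46, SYTL4 -8.09 (SE 2.15), HOXD1 -5.89 (SE 2.04), POLG -4.23 (SE 0.48) and PCDHB2 -4.18 (SE 0.38). The SE of KLHDC7B, RAB12, SYTL4 and HOXD1 is above 1, and the size of their changes is uncertain. PLA2G12A and PCDHB2 were also among the extremes with MS7126N1, in the same direction and against the same DMSO libraries. With MS7126N2, against the same DMSO libraries, PLA2G12A stood at 0.64 (SE 0.35), and the difference of MS7126 from MS7126N2 was 2.85 (SE 0.46). A trait of the DMSO libraries cancels in that difference, which argues against it as the whole cause for PLA2G12A. As PLA2G12A was also among the highest with C24 and MS7126N1, a part from such a trait stays open. For PCDHB2 an effect of MS7126 and a trait of the DMSO libraries cannot be told apart here. With MS7126 in Huh7, PLA2G12A stood at -1.03 (SE 0.29).

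The sterol genes were higher with C24. Of 21 cholesterol synthesis genes, 14 rose and none fell (16 adjusted over the list alone), with a median log2 fold change of 0.45 (cameraPR adjusted p = 1.5e-25). The authors' deposited table gave FDFT1 0.64 (SE 0.10), ACAT2 0.74 (SE 0.12) and IDI1 0.79 (SE 0.17). Fatty acid synthesis had 7 of 15 higher (7 adjusted over the list alone, cameraPR adjusted p = 1.27e-11), and NRF2 targets 7 of 17 (9 higher and 1 lower adjusted over the list alone, cameraPR adjusted p = 1.67e-13), with AKR1C1 at 0.84 (SE 0.09) and FTH1 at 0.60 (SE 0.08) in the authors' deposited table. Hepatocyte markers had 4 of 22 higher and none lower (6 adjusted over the list alone, cameraPR adjusted p = 1.67e-08). The authors' deposited table for C24 held 245 higher and 327 lower genes of 8146 tested, led by PLA2G12A 2.45 (SE 0.30) and ASL 2.32 (SE 0.27), and, lower, the clock gene PER1 -4.19 (SE 0.40) and ZNF778 -3.98 (SE 0.36).

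MS7126 and C24 were compared at the same dose and time. Their log2 fold changes differed in 898 of 14335 genes, 363 higher and 535 lower under MS7126 (adjusted p of a normal test on the summed variances). That test ignores the covariance from the shared DMSO libraries; with a covariance for them 2209 genes differed. Among cholesterol synthesis genes, 19 of 21 were lower under MS7126 than under C24, with a median difference of -2.01, and 19 of 24 ATF4 targets were higher, with a median difference of 1.47. The difference was -2.59 for HMGCS1 (95% interval -3.16 to -2.03) and -2.32 for SQLE (-2.71 to -1.92), and 2.92 for ASNS (2.38 to 3.46). For EZH2 mRNA the interval was -0.75 to 0.74. The gene lists of the difference were counted, not tested as lists. The comparisons share their DMSO libraries: the correlation of their log2 fold changes across genes was 0.31 against 0.48 simulated with no effect, with a covariance of 0.0725 against 0.0503. They shared 49 higher and 75 lower genes, against 21.7 and 38.1 for independent lists, while 65 genes lower under MS7126 were higher under C24 and 20 went the other way. Among genes with a mean of at least 100, simulated groups with no effect shared 0 calls. Such groups yield few calls of any kind, so this does not measure what the shared DMSO libraries add to the overlap.

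The analogs without PROTAC activity gave few calls. In the authors' deposited tables MS7126N1 had 14 higher and 16 lower genes and MS7126N2 had 54 and 51 (30 and 43 at 2-fold or more). Of 18817 and 18528 genes, 435 and 759 had an unadjusted p under 0.05, in each case a share below the 0.05 that chance gives. For MS7126N1 the authors' deposited table was led by CBX5 2.58 (SE 0.42) and PLA2G12A 2.31 (SE 0.37), and, lower, PER1 -4.93 (SE 0.42) and PCDHB2 -3.73 (SE 0.37). No cholesterol synthesis gene was called with MS7126N1, over all genes or adjusted over the list alone, and the median was 0.04. With MS7126N2 the list was lower, at a median of -0.37 (cameraPR adjusted p = 1.9e-10), with no member called over all genes and 3 lower adjusted over the list alone, and 10 of 24 ATF4 targets rose (16 adjusted over the list alone, cameraPR adjusted p = 1.36e-51). The authors' deposited table for MS7126N2 gave ASNS 1.91 (SE 0.18) and TRIB3 1.00 (SE 0.15). Against MS7126N1, MS7126 differed in 631 genes (252 higher, 379 lower), 18 of them cholesterol synthesis genes, all lower. Against MS7126N2, MS7126 differed in 266 genes (89 higher, 177 lower), 10 of them cholesterol synthesis genes, all lower. With a covariance for the shared DMSO libraries, 1850 and 968 genes differed. Among genes tested in both, 41 of 51 higher and 31 of 49 lower calls of MS7126N2 were shared with MS7126, against 3.78 and 3.96 for independent lists. For MS7126N1, 5 of 12 and 7 of 14 were shared, against 0.89 and 1.13. The correlation of log2 fold changes with MS7126 was 0.58 for MS7126N2 and 0.26 for MS7126N1, against 0.47 and 0.48 simulated with no effect and shared controls. The difference in HMGCS1 was -2.07 (95% interval -2.66 to -1.48) from MS7126N1 and -1.23 (-1.88 to -0.58) from MS7126N2.

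**Figure D2:**
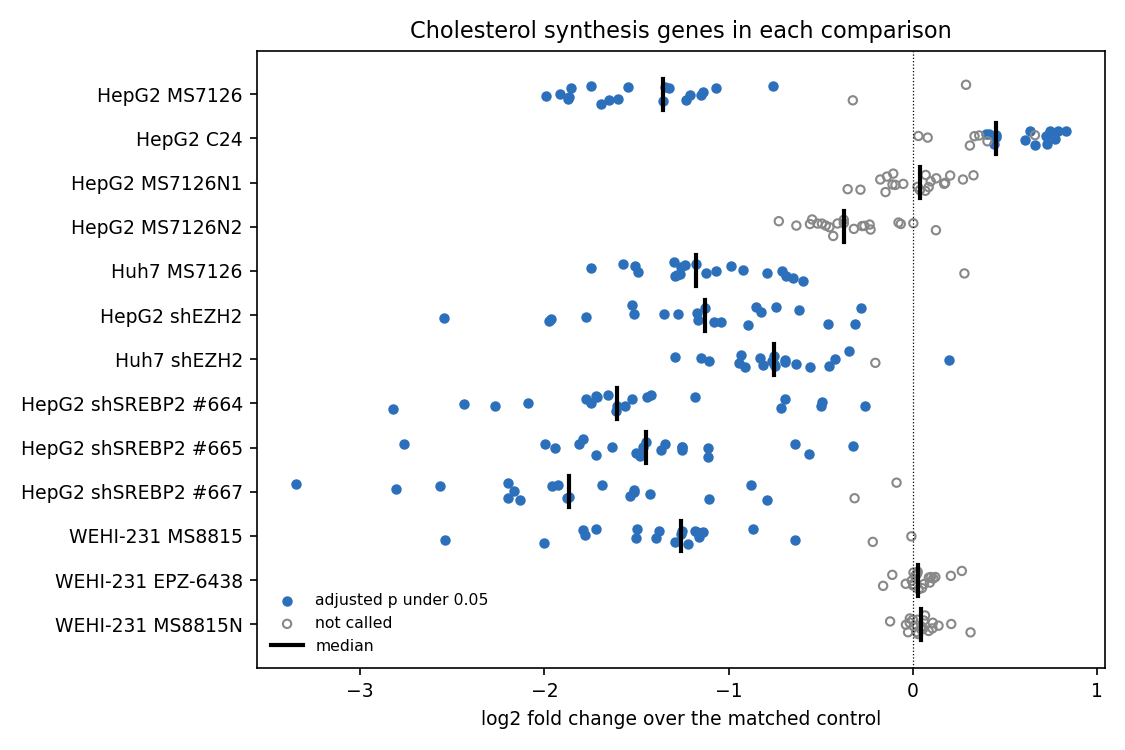
Log2 fold change over control of each measured cholesterol synthesis gene (points; filled where the adjusted p is under 0.05) in the 13 comparisons, with the median as a bar. The medians run from -1.86 with hairpin #667 to 0.45 with C24.

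MS7126 was also given to Huh7, the other liver line. Cholesterol synthesis had 20 of 21 members lower (20 adjusted over the list alone) at a median of -1.18 (cameraPR adjusted p = 2.59e-25), ATF4 targets 23 of 25 higher and 1 lower (23 and 1 adjusted over the list alone, cameraPR adjusted p = 6.97e-37), DNA replication 29 of 33 lower (29 adjusted over the list alone, cameraPR adjusted p = 1.14e-17) and immediate early genes 10 of 11 higher (10 adjusted over the list alone, cameraPR adjusted p = 1.74e-20). The authors' deposited table gave FDFT1 -1.51 (SE 0.10), MVK -1.75 (SE 0.15) and the insulin-induced sterol regulator INSIG1 -2.03 (SE 0.15). Among ATF4 targets, the authors' deposited table gave GDF15 2.69 (SE 0.12) and STC2 3.74 (SE 0.22). Genes of the unfolded protein response had 10 of 17 lower and 2 higher (10 and 2 adjusted over the list alone, cameraPR adjusted p = 5.57e-05), with HSPA5, the chaperone BiP, at -0.96 (SE 0.11) in the authors' deposited table. NRF2 targets had 10 of 17 lower and 3 higher (11 and 4 adjusted over the list alone, cameraPR adjusted p = 0.0475), and 14 of 22 hepatocyte markers were lower (15 adjusted over the list alone, cameraPR adjusted p = 3.82e-06). Of 8 AHR and PXR targets 3 rose and 1 fell (3 and 1 adjusted over the list alone, cameraPR adjusted p = 6.66e-05), with the xenobiotic-induced gene CYP1A1 at 3.12 (SE 0.12) in the authors' deposited table. Against random lists matched on expression, the NRF2 and the AHR and PXR lists did not pass (adjusted p = 0.0519 and 0.158).

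The authors' deposited table held 2797 higher and 2606 lower genes of 15956 tested for Huh7 MS7126, led by IL11 7.56 (SE 0.79), ARRDC4 5.29 (SE 0.71), IGFBP1 4.28 (SE 0.44) and TXNIP 4.21 (SE 0.21), and, lower, by SYTL4 -7.72 (SE 1.38), a change of uncertain size, and ARPIN -5.45 (SE 0.32). HepG2 and Huh7 shared 540 higher and 643 lower genes, against 186 and 195 for independent lists, while 41 higher and 26 lower in HepG2 went the other way in Huh7, with a correlation of 0.56 across 8972 genes. The times differed (48 and 24 h by the samples' own labels), and the log2 fold changes differed in 992 of 13150 genes.

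With shEZH2 in Huh7, cholesterol synthesis genes were lower along with EZH2. Of 21 members, 19 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 4.14e-19). The list passed with an estimated correlation as well, camera adjusted p = 0.0296, the only one of 9 passing lists to do so. That adjustment ran together with the other comparisons at the preset correlation of 0.01. Adjustment over the Huh7 shEZH2 lists alone was not run, so whether the list would pass there is not known. HMGCS1 stood at -0.69 (SE 0.02), MVD at -1.29 (SE 0.04) and MSMO1 at -1.11 (SE 0.03) by edgeR. Of 9 sterol-responsive genes outside synthesis all fell, over all genes and adjusted over the list alone (camera adjusted p = 6.01e-08, adjusted p = 0.081 with an estimated correlation). Fatty acid synthesis had 13 of 16 lower (15 adjusted over the list alone, camera adjusted p = 6.33e-11, adjusted p = 0.0512 with an estimated correlation), with ACSS2 at -2.43 (SE 0.09) and SCD at -0.64 (SE 0.02). ATF4 targets fell, 16 of 25 lower and 1 higher (16 and 1 adjusted over the list alone, camera adjusted p = 4.58e-05, adjusted p = 0.098 with an estimated correlation). Hepatocyte markers had 15 of 22 lower and 3 higher (15 and 4 adjusted over the list alone, camera adjusted p = 4.96e-07, adjusted p = 0.0776 with an estimated correlation), with ALB at -0.53 (SE 0.01) and APOA2 at -1.33 (SE 0.04). Of the 13 transcripts of the mitochondrial genome 12 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 4.26e-09, adjusted p = 0.267 with an estimated correlation).

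By edgeR, 2838 genes were higher and 2811 lower in Huh7 shEZH2 of 14581 tested (3095 and 2566 after centring, 611 and 228 at 2-fold or more). The groups did not overlap in 10003 of the 14581, where chance gives a share of 33.3%. They did not overlap in 5644 of the 5649 called genes, which were called on the same values. The authors' deposited table held 1702 higher and 1721 lower genes, of which 3420 were also called by edgeR. HEPACAM2 rose from 12.1 ± 0.22 to 213 ± 23.6 normalized counts (SD, n = 2 each; 4.13, SE 0.20), SLPI from 67.4 ± 18.0 to 751 ± 14.7 (3.49, SE 0.11) and MUC12 by 3.68 (SE 0.17). AFM, a plasma vitamin E binding protein gene, fell from 350 ± 1.7 to 43.4 ± 2.9 (-3.01, SE 0.12), and SERPINC1, the antithrombin gene, by 2.32 on the log2 scale (SE 0.08).

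The libraries labelled shEZH2 in HepG2 held 4931 higher and 4955 lower genes of 17348 in the authors' deposited table (5615 and 4249 after centring, 2419 and 1222 at 2-fold or more), with a median over genes with at least 100 normalized counts of -0.10. Relative to that shift the cholesterol synthesis median was -1.03, and all 21 genes fell, over all genes and adjusted over the list alone, at a median of -1.13 as deposited (cameraPR adjusted p = 7.42e-20). The authors' deposited table gave HMGCS1 (chromosome 5, 43289395 to 43313512, minus strand) -2.55 (SE 0.07) and ACAT2 -1.96 (SE 0.06), while IGFBP3 was 4.90 (SE 0.21) and TUBA1A -4.15 (SE 0.19). Other extremes in the authors' deposited table were UTP14C 11.40 (SE 1.46), ZFP91-CNTF 10.84 (SE 1.03) and ISY1-RAB43 -10.84 (SE 1.45), whose levels are uncertain where reads were split with overlapping or near-identical genes, which was not tested. DNA replication genes had 26 of 33 lower and 3 higher (26 and 3 adjusted over the list alone, cameraPR adjusted p = 3.27e-08), with TYMS at -2.66 (SE 0.07) in the authors' deposited table. Against the authors' deposited table for Huh7 shEZH2 the log2 fold changes correlated at 0.04 across 8641 genes, and 455 higher and 769 lower genes were shared, against 379 and 579 for independent lists. Another 396 higher and 489 lower in HepG2 went the other way in Huh7. With the edgeR calls for Huh7, chosen after seeing the data, 721 and 1176 were shared, against 626 and 933 for independent lists, and 627 and 790 went the other way. Against HepG2 MS7126 the correlation was -0.13, and 204 higher and 345 lower genes were shared, against 255 and 378 for independent lists, while 422 higher and 432 lower in the libraries labelled shEZH2 went the other way under MS7126.

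Cholesterol synthesis genes were lower with the 3 SREBP2 hairpins: 21, 21 and 19 of 21 fell with #664, #665 and #667, the same counts adjusted over the list alone, at medians of -1.61, -1.45 and -1.86 (cameraPR adjusted p = 1.79e-53, 1.28e-53 and 1.05e-65). The authors' deposited tables gave HMGCS1 -2.82 (SE 0.06), -2.76 (SE 0.16) and -3.35 (SE 0.14). Fatty acid synthesis genes had 13, 12 and 10 of 15 lower and 2, 1 and 1 higher (the same adjusted over the list alone, cameraPR adjusted p = 1.4e-37, 2.25e-17 and 1.67e-13), with SCD at -2.46 (SE 0.02), -1.33 (SE 0.09) and -1.11 (SE 0.09) in the authors' deposited tables. Hypoxia genes rose, 15, 11 and 15 of 18 higher and 2, 2 and 1 lower (the same adjusted over the list alone, cameraPR adjusted p = 4.6e-09, 0.00988 and 5.19e-21), with NDRG1 at 2.18 (SE 0.06), 0.89 (SE 0.12) and 2.22 (SE 0.11) in the authors' deposited tables. With an inter-gene correlation of 0.05 the hypoxia list of #665 did not pass (adjusted p = 0.0577). The authors' deposited tables held 4399 higher and 4740 lower genes for #664, 3233 and 3452 for #665, and 3072 and 3184 for #667. After centring on the median gene, more genes were higher than lower with each, 4968 and 4136, 3791 and 2783, and 3435 and 2768, as at 2-fold or more without centring, 1463 and 676, 1278 and 421, and 1167 and 583. Called with all 3 hairpins were 1724 higher and 1987 lower genes, and 3555 of the 3709 of these that were measured in the HepG2 libraries labelled shEZH2 were called the same way there. The libraries labelled shEZH2 shared 3198 higher and 3654 lower genes with #664, against 1195 and 1369 for independent lists, while 156 and 214 went the other way. Among genes with a mean of at least 100, simulated groups with no effect and shared controls had 0 calls in common. Groups with no effect yield few calls of any kind, so this does not measure what shared controls add to the overlap.

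All 13 transcripts of the mitochondrial genome were higher in each of the 4 HepG2 hairpin comparisons, with medians of 2.32 for the libraries labelled shEZH2 and 1.72, 2.03 and 1.78 for #664, #665 and #667 (cameraPR adjusted p = 8.69e-60, 7.42e-141, 3.78e-34 and 1.96e-32; 13 adjusted over the list alone in each). Against random lists matched on expression, the list passed for #665 (adjusted p = 0.00137) and not for the others (adjusted p = 0.758, 0.548 and 0.556). Those lists came from neighbouring expression ranks and could hold the mitochondrial transcripts themselves. A failure there does not set the rise down to chance. The log2 fold changes of the libraries labelled shEZH2 correlated with those of the 3 hairpins at 0.81, 0.86 and 0.79 across genes, against 0.46, 0.46 and 0.45 simulated with no effect, with covariances of 0.456, 0.444 and 0.427 against 0.0106, 0.0130 and 0.0135. Genes are not independent replicates, and part of any excess in shared calls can come from the shared controls. SREBF2 differed between the libraries labelled shEZH2 and the hairpins by 2.01 (95% interval 1.32 to 2.70), 1.52 (0.80 to 2.24) and 2.78 (1.72 to 3.85).

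With MS8815 in WEHI-231, cholesterol synthesis genes fell, 19 of 21 lower (19 adjusted over the list alone) at a median of -1.26 (cameraPR adjusted p = 1.27e-168). The authors' deposited table gave the lanosterol synthase gene Lss -2.54 (SE 0.11), Hmgcs1 -1.79 (SE 0.07) and Idi1 -1.72 (SE 0.06). Sterol-responsive genes outside synthesis had 5 of 7 lower (6 adjusted over the list alone, cameraPR adjusted p = 1.52e-27), with Insig1 at -1.55 (SE 0.08) in the authors' deposited table, while LXR targets had 3 of 6 higher (4 adjusted over the list alone, cameraPR adjusted p = 0.00139), with the cholesterol exporter genes Abca1 at 0.88 (SE 0.12) and Abcg1 at 0.72 (SE 0.14) in the authors' deposited table. ATF4 targets had 15 of 22 higher (17 adjusted over the list alone, cameraPR adjusted p = 1.23e-25), with Trib3 at 2.30 (SE 0.19) and Ddit3 at 1.76 (SE 0.18) in the authors' deposited table. DNA replication had 24 of 33 lower (27 adjusted over the list alone, cameraPR adjusted p = 1.29e-27), and PRC2 subunits 4 of 12 lower (4 adjusted over the list alone, cameraPR adjusted p = 0.00876). The LXR list did not pass on ranks (adjusted p = 0.1), nor did the PRC2 list against random lists (adjusted p = 0.0845). The authors' deposited table held 570 higher and 1259 lower genes of 10671 tested, 31.2% higher; centring on the median gene gave 715 higher and 860 lower, 45.4% higher. At 2-fold or more 98 were higher and 43 lower.

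EPZ-6438 gave 18 higher and 18 lower genes (11 and 5 at 2-fold or more) and MS8815N 8 and 11 in the authors' deposited tables. Of 16034 and 15954 genes, 454 and 346 had an unadjusted p under 0.05, in each case a share below the 0.05 that chance gives. No cholesterol synthesis gene was called with EPZ-6438 or MS8815N, over all genes or adjusted over the list alone, at medians of 0.03 and 0.05. The MS8815N list passed (cameraPR adjusted p = 0.00838) but not with a larger correlation between genes of 0.05 (adjusted p = 0.0591) or against random lists (adjusted p = 0.0509). ATF4 targets were higher with MS8815N as a list, with no member called (cameraPR adjusted p = 1.14e-07, median 0.10). MS8815 differed from EPZ-6438 in 525 of 13096 genes, 149 higher and 376 lower (28.4% higher, 39.0% after centring), and from MS8815N in 334, 86 higher and 248 lower (25.7% higher, 37.7% after centring). With a covariance for the shared DMSO libraries, 1424 and 1192 genes differed. In each case 18 of 21 cholesterol synthesis genes were lower under MS8815. EPZ-6438 and MS8815N were not compared with each other.

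**Figure D3:**
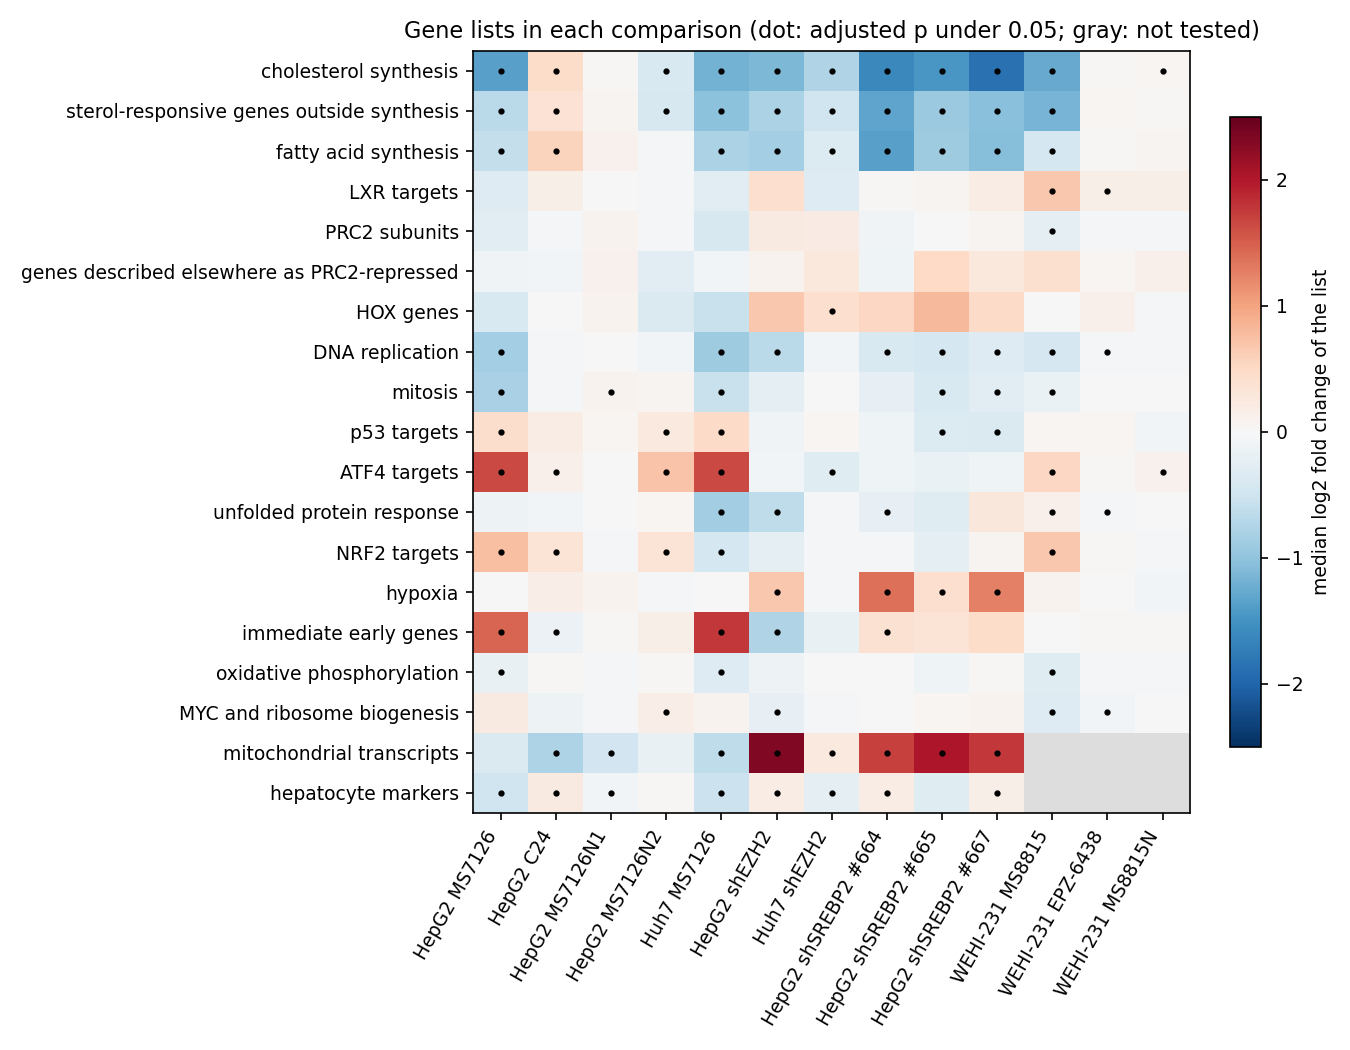
Median log2 fold change over control of 19 gene lists (rows) in the 13 comparisons (columns). A dot marks an adjusted p under 0.05 by cameraPR (by camera for Huh7 shEZH2), and gray marks lists not tested. Cholesterol synthesis is lower in 9 comparisons and higher with C24 and, slightly, MS8815N, and mitochondrial transcripts are highest in the 4 HepG2 hairpin comparisons.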

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

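The test of GC content and length was set before its result was seen, and all other tests of explanations in this part after. SREBF2 and EZH2 were picked after their values were seen. Under MS7126, the log2 fold changes of 992 genes differed between HepG2 and Huh7. For SREBF2 the difference was -0.62, lower in HepG2. Under shEZH2, 6109 genes differed between the HepG2 libraries so labelled and Huh7, by the authors' deposited tables of both. The difference, HepG2 minus Huh7, was 3.56 for EZH2 and 0.94 for SREBF2. Each passed a test of the difference itself, and under MS7126 the cell line and the time cannot be told apart. No group holds enough libraries to test a single library as outlying.

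EZH2 mRNA was higher than control in the HepG2 libraries labelled shEZH2. A reversed sign is argued against, since with the sign turned the rebuilt control levels differ from those of the #664 table by an interquartile range of 0.949 on the log2 scale. An exchange with a control library is argued against, since the standard error of EZH2 lay at most 0.136 above the trend in the #664 and #665 tables, which share the controls (0.559 for #667). A labelled library at the control level beside a lowered one is argued against, since their average would not exceed control and the 95% interval of the log2 fold change starts at 0.15. The standard error of EZH2 lay 2.04 above the trend in this table, and that of SREBF2, not the target there, 2.64; a labelled library from outside these groups may be a candidate explanation, which stays open as values per library were not analysed here, as does higher EZH2 mRNA as a biological effect, which was not tested.

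The 4 HepG2 hairpin comparisons moved together across genes. Chance values shared through the control libraries are argued against as the whole cause, since the observed covariance was at least 19.2 times the simulated one in all 6 pairs. A trend with GC content or length is argued against as the whole cause, since the smallest correlation was 0.788 after it was removed, with GC content known for 97.9% of genes. A library batch that parts the controls from the hairpin libraries cannot be told apart from the hairpins, since the labels name 2 library kits without saying which library used which: the smallest median of mitochondrial transcripts over the 4 tables was 1.72. A response shared by the hairpins stays open and untested.

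In the HepG2 compound tables some genes had standard errors far above the trend. RNA of myeloid cells may be a source. Of the members noticed in the tables beforehand, 12 of 15 lay at least 1 above the trend (log2) in all 4 tables, which share their DMSO libraries. Among them were PRTN3 and SRGN at means of 196 and 249 with MS7126. As these members were picked from the same values, their share is no test. Of those not noticed, 3 of 13 lay that far above the trend in all 4, 23.1% (exact 95% interval 5.04% to 53.8%). The abundant LYZ and CYBA, at means of 7369 and 9073, lay near the trend, but levels that high in these libraries would hide a small share from other cells. Capture of RNA without a poly(A) tail may be another: with MS7126, 5 of 21 histone genes not noticed beforehand lay that far above the trend, 23.8% (8.22% to 47.2%), against 2.62% of all genes, and 28.6% to 42.9% did in the other 3 tables. Both shares lie under the 25% set as the bound for exclusion, but their intervals reach past it; the interval was brought in after the shares were seen, so both stay open, and no biological explanation was tested.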

How the results depend on the processing

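The authors' own adjusted p and statistic for Huh7 shEZH2, the crossed pairing, the edgeR values of Huh7 shEZH2 set against the HepG2 libraries labelled shEZH2, and the use of hairpins #664 and #665 alone were chosen after seeing the data. EZH2 in each comparison and SREBF2 with the 3 hairpins against it kept their sign under the alternatives run on them, and no list that had passed did so in the opposite direction under an alternative. The balance of higher and lower calls did turn. After centring and at 2-fold or more, higher calls outnumbered lower ones in the 4 HepG2 hairpin comparisons; at 2-fold or more they also did for HepG2 MS7126 (428 and 422) and MS8815 (98 and 43), and lower calls did for MS7126N2 (30 and 43). Equal numbers with EPZ-6438 became 18 and 15 after centring and 11 and 5 at 2-fold or more, and MS7126N2 had 52 each after centring. At 2-fold or more, where fewer genes can pass by construction, 850 genes were called for HepG2 MS7126, 59 for C24, 2026 for Huh7 MS7126, 3641 for the HepG2 libraries labelled shEZH2, 839 for Huh7 shEZH2, 141 for MS8815 and 16 for EPZ-6438. Hairpins #664, #665 and #667 gave 2139, 1699 and 1750. An adjusted p under 0.01, also stricter by construction, left 1261 for HepG2 MS7126, 272 for C24, 18 for MS7126N1, 61 for MS7126N2 and 1197 for MS8815. Adjusting over genes with a mean of at least 100 left 23 for EPZ-6438 and 6 for MS8815N. For Huh7 shEZH2, 3424 genes were called by DESeq2 and 3423 in the authors' deposited table, against 5649 by edgeR; the cause was not tested.

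With a covariance for shared controls, MS7126 differed from C24, MS7126N1 and MS7126N2 in 2209, 1850 and 968 genes, and MS8815 from EPZ-6438 and MS8815N in 1424 and 1192. The smaller variance of the difference follows from that setting. At 2-fold or more, MS7126 shared 17 calls with C24, 42 with MS7126N2, 328 with Huh7 MS7126 and 65 with the HepG2 libraries labelled shEZH2. MS8815 shared 1 with EPZ-6438 and 0 with MS8815N, and the libraries labelled shEZH2 in the 2 liver lines, by the authors' deposited tables, shared 36. By edgeR for Huh7, with more calls there, these lines shared 1897 calls with no fold minimum and differed in 6982 genes. At 2-fold or more, the HepG2 libraries labelled shEZH2 shared 1417, 1355 and 1163 with #664, #665 and #667. Hairpin #664 shared 930 with #665 and 1034 with #667, #665 and #667 shared 810, and all 3 shared 629. MS7126N1 and MS7126N2 shared 2 among genes with a mean of at least 100.

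Against random matched lists, passes were counted over all lists tested, so they need not be among the lists that passed cameraPR. With the cameraPR count second, they numbered 2 and 4 for MS7126N1 and 7 and 14 for the HepG2 libraries labelled shEZH2. Hairpin #664 had 5 and 13, and #665 had 7 and 11. MS8815 had 10 and 17, EPZ-6438 had 0 and 4, and MS8815N had 1 and 3. The cause of the lower counts was not tested. With an estimated correlation 1 of 9 passed for Huh7 shEZH2, adjusted together with the other comparisons at the preset correlation. Cholesterol synthesis with MS8815N was lost at an inter-gene correlation of 0.05 (adjusted p = 0.0591) and against random lists (adjusted p = 0.0509), the cause of either not tested. Of the other list tests under an alternative, 671 stayed on their side of the threshold, 108 were lost and 2 were gained.

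Without 1 library at a time, with the lone library assumed to vary like the others, the genes called in Huh7 shEZH2 numbered 4621 to 4866, and EZH2 in Huh7 shEZH2 stood at -2.72 to -2.60. The replicate numbers do not establish a pairing, as same-numbered deviations correlated at -0.024. With the replicate number as a block 5427 genes were called, and with crossed pairing 5905. Libraries were not left out in the other 12 comparisons, whose values and depth per library were not analysed here.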

Other observations

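In Huh7 shEZH2, 11 of 18 HOX genes, developmental regulators, were higher and 2 lower (12 and 2 adjusted over the list alone, camera adjusted p = 0.00657, adjusted p = 0.177 with an estimated correlation). By edgeR, HOXC6 stood at 1.75 (SE 0.14) and HOXD1 at 1.66 (SE 0.08). Biliary markers had 5 of 7 higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.199 with an estimated correlation), with SPP1 at 1.35 (SE 0.11) and KRT19 at -0.95 (SE 0.10). Among genes with a mean of at least 100 this list did not pass (camera adjusted p = 0.0528, biliary markers in Huh7 shEZH2). In the 4 HepG2 hairpin comparisons, lysosome genes had 12, 11, 11 and 11 of 20 members lower for the libraries labelled shEZH2, #664, #665 and #667 (12, 11, 12 and 11 adjusted over the list alone, cameraPR adjusted p = 0.00795, 0.0477, 0.0018 and 0.00224). Against random lists none of these passed (adjusted p = 0.209, 0.332, 0.382 and 0.241). The sialidase gene NEU1 stood at -1.12 (SE 0.05), -0.80 (SE 0.04), -0.97 (SE 0.11) and -1.18 (SE 0.10) in the authors' deposited tables. Mesenchymal markers had 5 members lower in each of the 4, of 9, 10, 9 and 9 measured, and 3, 3, 2 and 2 higher (5 lower and 3, 4, 2 and 2 higher adjusted over the list alone, cameraPR adjusted p = 0.0204, 0.000228, 0.0157 and 0.000127). The test was downward for #664 although its median was 0.06, and against random lists none passed (adjusted p = 0.402, 0.961, 0.118 and 0.0587).

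Under MS8815 in WEHI-231, 20 of 33 oxidative phosphorylation genes were lower (26 adjusted over the list alone, cameraPR adjusted p = 6.45e-14), as were 14 of 16 MYC and ribosome biogenesis genes (15 adjusted over the list alone, cameraPR adjusted p = 4.26e-15). The authors' deposited table gave Atp5b -0.50 (SE 0.04) and Npm1 -0.31 (SE 0.05). NRF2 targets had 7 of 14 higher and 2 lower (10 and 2 adjusted over the list alone, cameraPR adjusted p = 4.96e-07), with Nqo1 at 5.09 (SE 0.69) and Osgin1 at 4.90 (SE 0.65) in the authors' deposited table. Mitochondrial transcripts were lower as a list with C24, at a median of -0.78 (cameraPR adjusted p = 0.000761), and with MS7126N1, at -0.48 (cameraPR adjusted p = 4.16e-09), with 0 of 13 members called in either, over all genes or adjusted over the list alone. Both passes rest on the preset inter-gene correlation, as none was estimated there. In Huh7 shEZH2, where it was estimated, the mitochondrial list did not pass with it. The clock gene PER1 was among the lowest called genes with C24, MS7126N1 and MS7126N2, at -4.19 (SE 0.40), -4.93 (SE 0.42) and -4.43 (SE 0.43) in the authors' deposited tables. These 3 comparisons and HepG2 MS7126, where PER1 was also lower, at -3.83 (SE 0.47) in the authors' deposited table, share their DMSO libraries. With MS7126 in Huh7 PER1 stood at -0.08 (SE 0.38) in the authors' deposited table and was not called; both MS7126 values were picked after they were seen.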
